A study of Mus musculus with 8 samples.

How the data were processed

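Single cells carrying CD45, a protein on the surface of white blood cells, were taken with magnetic beads from E0771.lmb mammary tumours 14 to 16 days after injection, per the labels. The mice were Shb flox/flox with Vav1-cre, which acts in blood-forming cells (KO), or without Shb loss (WT). The series holds 8 samples in 2 experiments. The 4 samples of experiment 1 had the counts used here, 2 KO and 2 WT libraries, and the matrices of the 4 samples of experiment 2 were not used here. The deposited values were counts, whole numbers of UMIs (unique molecular tags) per gene and cell, made with 10x 3' v3.1 chemistry. The submitters' processing notes name Cell Ranger 4.0.0 and mm10, and the gene annotation version and cell-calling settings were not stated. The labels give 10000 cells for each library. In the order KO replicate 1, KO replicate 2, WT replicate 1, WT replicate 2, the libraries held 12052, 3032, 7767 and 6658 barcodes and 61091178, 32198422, 72724001 and 63698082 UMIs.

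Cells with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs were kept. Doublets (droplets with more than 1 cell) were scored with scrublet in scanpy 1.11.5 at an expected 8%. The caller did not work on these data: it called 0, 0, 1 and 0 doublets, so doublets largely remain. Counts were log-normalised and clustered jointly without integration, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1 with seed 1, which gave 27 clusters. T and NK clusters were clustered again on their own. A cluster took a cell type's name from marker lists fixed before the data were examined, where at least 3 markers were found in at least 10% of its cells at a log2 fold of at least 1 over other clusters, after 10 CPM (counts scaled to a common library size) were added. It stayed unnamed where over 90% of its cells came from 1 library, where its median doublet score was at least 0.2, where none of its top 10 genes was a marker of the name or more were markers of another class, or where at least 2 of its 3 leading marker genes belonged to another class. Of these, T and NK subclusters were held only to the count of markers of another class, and stayed unnamed where natural killer genes came with Cd3 genes. Of low-UMI subclusters at least 1 marker among the top 10 genes was asked. These naming rules were set after the data were seen. Names therefore mean cells with such markers and are written with "-like". Unnamed clusters of at least 1000 cells were compared by their number, except those with nearly all cells from 1 library.

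Counts were summed per library and class, and cells were never treated as replicates. The 12 classes with at least 30 cells in every library, and all cells together, were tested for genotype with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment within a class and a limit of 0.05. All gene and share tests were two-sided. Shares of cells were tested with edgeR on cell numbers and are given with exact binomial intervals at a 95% level, which cover counting error only. A count of 0 was taken to allow up to 3 counts, over the group, and folds against 0 are lower bounds from that floor. T cell ratios were compared with an exact two-sided permutation test (scipy 1.17.1). The 39 gene lists were fixed before the data were examined, and lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a correlation of 0.01, with an estimated correlation and with fry, adjusted over all lists and classes. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scikit-image 0.26.0 and matplotlib 3.10.9 were also used.

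Genes were named by a rule fixed before the data were examined. Shb came first. In the 3 classes with the most cells, up to 8 higher and 8 lower genes with the smallest adjusted p were taken, and in the other classes and over all cells up to 3 each way, among passing genes whose KO values both lay beyond both WT values. Groups with fewer than 3 such genes give the 3 smallest p in each direction as not passing. Up to 4 members with the smallest p were eligible for each called list. Ribosomal protein, mitochondrial, predicted, receptor segment, haemoglobin and sex-linked genes were named only as groups. Pdlim4 in migratory dendritic-like cells falls outside the rule and was chosen after its values were seen.

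The tests were tested on simulated data with known changes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each class. The real fits called far fewer genes (2 over all cells), which makes the adjusted limit stricter. Recovery in the real data may therefore be lower than in these simulations. Over all cells edgeR recovered 31.3, 61.2 and 81.8% of 1.5-fold, 2-fold and 4-fold changes with 20 false calls of 136, and in macrophage-like cells 31.3, 68.7 and 93.9% with 15 of 144. In CD8-like cells it recovered 5.97, 34.3 and 92.4% with 8 of 96. Without KO replicate 1, 62 of 174 simulated calls over all cells were false. Leaving out the other libraries was not simulated. Alternatives were DESeq2 1.42.0, other size factors, no low-count filter, doublet calls kept, a 20% mitochondrial limit, cells thinned to 2000 UMIs, equal numbers of cells, Leiden resolution 0.5, a replicate block and leaving out each library. For shares they also included a minimum of 1000 UMIs, TMM, immune classes alone and limma on logit shares. A minimum of 3000 UMIs, leaving out the 8% of cells with the highest doublet scores, fry and a block with the numbers crossed were chosen after the data were seen. No batch or day is given in the labels. Each pair of libraries differed beyond sampling noise, so none is a copy of another.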

Results

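White blood cells of E0771.lmb mammary tumours were compared between mice lacking Shb in blood-forming cells (KO) and mice that kept it (WT). E0771.lmb is a mouse mammary tumour line, and Shb codes for an adaptor protein that passes on signals from tyrosine kinase receptors and from the T cell receptor. The comparison held 4 libraries of 1 experiment, 2 KO and 2 WT. Values for the 4 libraries are given in the order KO replicate 1, KO replicate 2, WT replicate 1, WT replicate 2. Cells kept numbered 11448, 2823, 7054 and 6167, with a median of 2531, 9803, 8626 and 8966 UMIs (counted RNA molecules) per cell. KO replicate 1 thus had the most cells and the lowest depth per cell. Log2 fold changes are KO over WT with the standard error of the edgeR fit, n = 2 against 2 libraries. In each named gene with a passing adjusted p, both KO values lay beyond both WT values, except where stated. Nothing in the labels shows whether the libraries came from separate animals, so the p-values measure the spread between these libraries only. Leaving out a library leaves 1 in its group, which is then assumed to vary as the 2 of the other group do, so a call kept there is weak support for it.

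Shb RNA was lower in the KO libraries of most myeloid classes and was not absent from the KO samples as a whole. Over all cells, Shb took 1.32, 1.14, 2.87 and 3.37 CPM (UMIs scaled to the total of the library or class), from 79, 36, 203 and 211 Shb UMIs. The log2 fold change was -1.34 ± 0.21, which did not pass (adjusted p = 0.287), with both KO values under both WT values. Summed over each group, the KO level over all cells was 40.5% of the WT level (95% exact interval 32.6 to 49.9%). These intervals pool the UMIs of the 2 libraries of a group and cover counting error only. In macrophage-like cells it was 2.99% (0.0741 to 17.6%; 1 against 43 UMIs). In monocyte-like cells it was 7.35% (1.48 to 22.3%; 3 against 72 UMIs), in conventional dendritic-like cells 6.86% (0.168 to 41.6%; 1 against 27 UMIs) and in migratory dendritic-like cells 7.38% (0.180 to 45.1%; 1 against 25 UMIs). Cluster 1 kept 25.9% (13.2 to 46.9%), with KO replicates 1 and 2 apart at 1.16 and 0.410 CPM (11 and 2 UMIs). Cluster 3 kept 45.3% (21.5 to 88.7%) and cluster 5 33.2% (3.58 to 152%). Where Shb was tested it did not pass as a gene of its class, with an edgeR adjusted p of 0.101 in macrophage-like, 0.173 in monocyte-like, 0.363 in cluster 1 and 0.783 in cluster 3 cells. In conventional dendritic-like, migratory dendritic-like and cluster 5 cells its counts fell under the low-count filter, so it was not tested there. CD4-like and CD8-like T cells had 0 Shb UMIs in all 4 libraries, so a loss in them was not detectable at this depth. The limit that a count of 0 allows in CD8-like cells was 3.64, 3.08, 1.07 and 2.56 CPM. Of the Shb UMIs of the KO libraries, 70.9% and 69.4% lay in classes that were not tested, against 24.1% and 30.3% in the WT libraries. The largest such source was unnamed cluster 13, led by Rhox5, Cald1, Krt8, Aebp1 and Sparc, with 12.3, 11.1, 7.07 and 15.9 CPM of Shb. It held 52 and 20 of the 79 and 36 Shb UMIs of the KO libraries. Its best-matching marker list was that of tumour epithelial cells, and cells in which Vav1-cre does not act would keep Shb. Shb (ENSMUSG00000044813) lies on chromosome 4 of mm10, from 45423278 to 45532470 on the minus strand. The deleted part is not given in the labels, and 3' reads that lie outside it would check nothing.

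**Figure D1:**
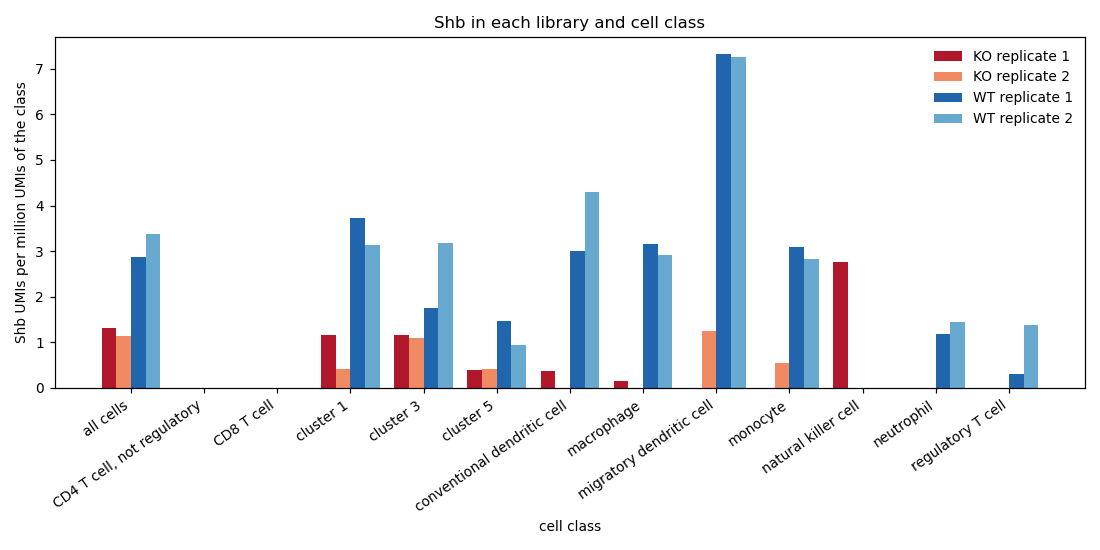
Shb CPM, the UMIs scaled to the class total (y axis), in the 4 libraries of every tested cell class (x axis), 1 bar per library. Over all cells the KO bars stand at 1.32 and 1.14 and the WT bars at 2.87 and 3.37.

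Regulatory T-like cells, which restrain other lymphocytes, made up 2.08, 4.39, 6.18 and 7.83% of the kept cells. Fibroblast-like cells, which make collagen, went the other way with 0.236, 0.248, 0.0425 and 0.0649%, from 27, 7, 3 and 4 cells. B-like cells numbered 3, 4, 15 and 11. Neither regulatory T-like (log2 fold change -1.12 ± 0.94, adjusted p = 0.801), fibroblast-like (2.14 ± 1.12, 0.392) nor B-like cells (-1.51 ± 1.15, 0.801) passed the edgeR test of cell numbers. With at least 3000 UMIs per cell the fibroblast-like share did pass in the edgeR test (3.47 ± 0.60, adjusted p = 0.0446). That call rests on very few WT cells, as the 3 cells of WT replicate 1 had a median of 1313 UMIs. Macrophage-like cells took 9.42, 15.1, 10.8 and 12.1%, monocyte-like cells 7.81, 16.7, 16.5 and 17.6% and conventional dendritic-like cells 3.57, 2.94, 4.00 and 4.61%. Neutrophil-like cells took 1.15, 1.74, 2.15 and 1.83%. CD8-like T cells took 0.90, 3.65, 3.52 and 2.48%, and natural killer-like cells 0.437, 1.88, 1.64 and 0.957%. Most classes had their lowest share in KO replicate 1, where unnamed clusters 0 and 6 held 40.6% of the cells and so lowered the other shares. Of 25 classes and clusters, 2 passed, both unnamed and both higher in the KO group through KO replicate 1. Unnamed cluster 0, led by Ccl12, C1qa, C1qb and Ms4a7, took 30.2, 1.59, 2.00 and 1.75% of cells (log2 fold change 3.09 ± 1.01, adjusted p = 0.0430). Unnamed cluster 6, led by Igkc, Igha, Jchain and Gzma, took 10.4, 0.567, 0.553 and 0.405% (3.52 ± 1.03, adjusted p = 0.0331). In both, KO replicate 2 stood close to the WT libraries, and its share of cluster 0 lay under both. Without KO replicate 1, WT replicate 1 or WT replicate 2, 0 classes passed, and without KO replicate 2, 23 of 25 did. In simulations at the spread seen between these libraries, edgeR recovered 16.7% of 4-fold changes of a share, so most such changes would have been missed.

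**Figure D2:**
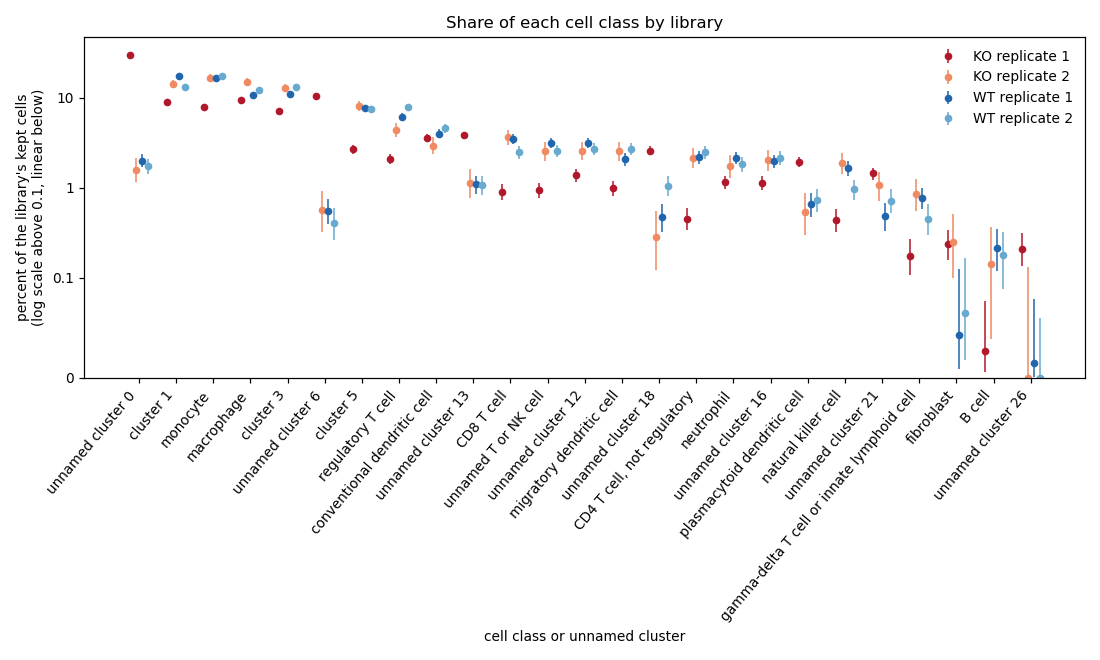
Percent of each library's kept cells (y axis, log scale above 0.1 and linear below) in every class and unnamed cluster (x axis), with exact 95% binomial intervals. KO replicate 1 stands apart in unnamed clusters 0 and 6, at 30.2% and 10.4% of its cells.

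The balance among T cells was measured as ratios of cell numbers. CD8-like to regulatory T-like cells stood at 0.433, 0.831, 0.569 and 0.317, a KO mean of 0.632 ± 0.281 (SD, n = 2) against 0.443 ± 0.178 in WT (exact two-sided permutation p = 0.667). CD8-like to CD4-like cells stood at 1.83 ± 0.207 against 1.31 ± 0.434 (SD, n = 2 each; exact two-sided permutation p = 0.333). These T cells made up 3.43, 10.2, 11.9 and 12.8% of kept cells, 6.82 ± 4.79% against 12.3 ± 0.645% (SD, n = 2 each; exact two-sided permutation p = 0.333). With 2 against 2 libraries, 0.333 is the smallest p these permutations can give, so no ratio could pass 0.05.

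Summed over all cells, Commd10 and Olfr56 were the 2 of 15475 genes that passed. Commd10, whose product helps sort proteins in endosomes, rose in the KO libraries (log2 fold change 1.75 ± 0.09, adjusted p = 0.0234) from 21.4 and 21.1 to 76.2 and 66.2 CPM. Olfr56, an olfactory receptor gene, fell (-4.11 ± 0.25, adjusted p = 0.0374) from 7.34 and 9.84 to 0.557 and 0.403 CPM. Both had an adjusted p of 0.0981 without WT replicate 2, where 0 genes passed. Without KO replicate 1, KO replicate 2 and WT replicate 1 the counts were 132, 245 and 12. With replicate number as a block neither Commd10 nor Olfr56 passed. At an unadjusted p under 0.05 there were 1197 genes, and DESeq2 called 153. Sva, a secreted protein gene, had 288 UMIs in the KO libraries and 0 in the WT libraries, at least 140-fold higher, and did not pass (adjusted p = 0.120). The heat shock gene Hspa1b (-0.71 ± 0.07, adjusted p = 0.146) did not pass either. Col5a3 (0.68), Cd302 (0.45), Ndufb1-ps (-0.69) and F7 (-0.78) were the other genes with the smallest p in their direction, and none passed.

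Genes of activated regulatory T cells were lower over all cells, in 20 of 21 tested members, with a median log2 fold change of -0.43. None passed over all genes, and 10 did adjusted over the list alone, among them Klrg1 (-0.50 ± 0.09), Icos (-0.43 ± 0.08), Tnfrsf9 (-0.49 ± 0.10) and Foxp3 (-0.66 ± 0.13), the factor that defines these cells. The set test (camera, correlation 0.01) gave an adjusted p of 2.6e-13, and 0.715 with an estimated correlation. Naive and memory T cell genes were lower in 14 of 16 members (median -0.25, adjusted p = 4.8e-06; 0.715 with an estimated correlation), with Satb1 at -0.60 ± 0.10 and Lef1 at -0.43 ± 0.13. Immediate early and T cell activation genes were lower in 18 of 20 (median -0.25, 1.3e-07; 0.715 with an estimated correlation), with the costimulatory receptor Tnfrsf4 at -0.47 ± 0.11 and the interleukin-2 receptor Il2ra at -0.47 ± 0.12. T cell RNA took 0.0627, 0.0784, 0.0970 and 0.0751% of UMIs, so these sums carry the share of T cells as well as levels within them. Hypoxia genes, which answer low oxygen, were lower in 17 of 18 members (median -0.21, 3.9e-07; 0.715 with an estimated correlation). Of these, 4 passed adjusted over the list alone: Ddit4 (-0.52 ± 0.06), Egln3 (-0.43 ± 0.08), Pdk1 (-0.28 ± 0.06) and Hilpda (-0.37 ± 0.08). Stroma genes were higher in 13 of 14 members (median 1.17, 4.0e-10; 0.715 with an estimated correlation). Collagen genes led them, with Col1a2 at 2.84 ± 0.56 and Col3a1 at 1.93 ± 0.51, beside the matrix genes Postn at 2.20 ± 0.57 and Sparc at 0.93 ± 0.24. Stroma RNA took 0.0325, 0.0642, 0.0203 and 0.0233% of UMIs. Macrophage genes were higher in 10 of 10 members (median 0.18, 4.6e-05; 0.715 with an estimated correlation), with the complement genes C1qb at 0.40 ± 0.09 and C1qc at 0.38 ± 0.09 and Ms4a7 at 0.38 ± 0.11. Macrophage RNA took 1.65, 1.58, 1.46 and 1.38% of UMIs. Unnamed cluster 0, led by C1qa, C1qb and Ms4a7 beside Ccl12, held 30.2% of the cells of KO replicate 1. The sums of stroma and macrophage genes thus also carry the shares of such cells. Stress genes of dissociation were lower in 20 of 24 (median -0.09, 1.4e-05; 0.715 with an estimated correlation) beside the immediate early genes, which handling can also induce. Both lists hold Fos, Fosb, Jun, Junb, Egr1, Ier2 and Nr4a1, so they are not separate results. Mitochondrially encoded genes, a measure of RNA quality, were lower in 10 of 11 (median -0.08, 2.9e-05; 0.715 with an estimated correlation) and took 2.50, 2.58, 2.72 and 2.64% of UMIs.

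Macrophage-like cells of the KO libraries held more Commd10 and Tgtp1 RNA and less Pdlim4, Mgl2, Klf4 and Hes1 RNA, and 11 of 11053 genes passed, 4 higher and 7 lower. Commd10 rose from 35.9 and 38.1 to 114 and 104 CPM (1.56 ± 0.10, adjusted p = 0.00176). Tgtp1, an interferon-induced GTPase gene, rose from 3.28 and 2.29 to 22 and 13.8 (2.69 ± 0.30, 0.0444). Pdlim4, which codes for an actin-bound adaptor, fell from 21.1 and 27.9 to 3.84 and 2.95 (-2.81 ± 0.24, 0.00809). Agpat4, a lipid synthesis gene, fell with -1.32 ± 0.15 (0.0444). The remaining 5 named genes fell at an adjusted p of 0.0448: the lectin gene Mgl2 (-0.79 ± 0.10) and the factor gene Klf4 (-0.88 ± 0.11), both marks of alternative activation, the Notch target Hes1 (-1.37 ± 0.18), the cytokine-induced inhibitor Cish (-1.12 ± 0.15) and Hspa1b (-0.73 ± 0.09). Without WT replicate 1 they no longer passed (Hspa1b 0.0698, Mgl2 0.0683, Hes1 0.0555, Cish 0.0589, Klf4 0.0624), and Hspa1b (0.106), Hes1 (0.0693) and Cish (0.0693) did not without WT replicate 2. Leaving out KO replicate 1, KO replicate 2, WT replicate 1 and WT replicate 2 gave 71, 392, 16 and 15 genes, holding 11, 11, 4 and 7 of the 11. Of the 11, 2 passed with the highest doublet scores left out, 2 at Leiden resolution 0.5, 2 with equal numbers of cells and 3 with thinned cells, and Commd10 passed in each of these. DESeq2 called 37 genes.

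Among gene lists in macrophage-like cells, alternative activation was lower in 15 of 18 members (median log2 fold change -0.43). The eotaxin gene Ccl24 (-2.08 ± 0.31), Pdcd1lg2, a ligand of PD-1 (-0.64 ± 0.16), and the lectin gene Chil3 (-0.76 ± 0.22) went with Mgl2. Mgl2 alone passed over all genes, and 5 did adjusted over the list alone. Camera gave an adjusted p of 1.6e-11, and 0.715 with an estimated correlation. Complement and tissue-resident genes were lower in 12 of 16 (median -0.36, adjusted p = 0.000189; 0.715 with an estimated correlation), with the factor Maf (-0.48 ± 0.10) and the chemokine Pf4 (-0.36 ± 0.12). Lipid-associated genes were lower in 15 of 19 (median -0.16, 0.00615; 0.715 with an estimated correlation), led by osteopontin, Spp1 (-0.97 ± 0.16), while the cholesterol exporter Abcg1 was higher (0.26 ± 0.09). Glycolysis genes were lower in 15 of 15 (median -0.14, 0.000194; 0.715 with an estimated correlation), with the lactate carrier Slc16a3 at -0.34 ± 0.09 and the hexokinase gene Hk2 at -0.50 ± 0.14. Immediate early genes were lower in 17 of 20 (median -0.29, 9.5e-07; 0.715 with an estimated correlation), with Nr4a1 (-0.51 ± 0.09), Fosb (-0.62 ± 0.13) and Egr2 (-0.95 ± 0.26). Genes of dissociation and heat shock stress, which tissue handling induces, were also lower, in 17 of 24 (median -0.18, 7.5e-08; 0.715 with an estimated correlation), with Ier3 at -0.59 ± 0.11 and Hspa1a at -0.63 ± 0.12. This list shares Nr4a1, Fosb and other members with the immediate early list. Type I interferon genes were higher in 24 of 26 (median 0.21, 1.8e-06; 0.715 with an estimated correlation), with Ifi44 (0.37 ± 0.09), Bst2 (0.36 ± 0.10) and Isg15 (0.39 ± 0.11), and none passed adjusted over the list alone. T cell receptor proximal genes were higher in 16 of 20 (median 0.35, 1.6e-05; 0.715 with an estimated correlation), with the signalling adaptor Fyb at 0.47 ± 0.10. T cell RNA took 0.00516, 0.00453, 0.00427 and 0.00326% of UMIs in these cells, also higher in the KO libraries. The list of interferon-gamma genes, higher in 21 of 23 (7.1e-06; 0.732 with an estimated correlation), lost its call without KO replicate 2 or WT replicate 2. The class pooled 3 clusters whose mix differed between libraries, so list results here carry that mix as well. Cluster 4 had 609, 343, 629 and 535 cells, the low-UMI cluster 10, led by Ctsk, Mmp9 and Acp5, 388, 54, 107 and 185, and cluster 23, led by Retnla, Ccl8 and Cd209f, 81, 30, 25 and 27.

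Monocyte-like cells of the KO libraries had more Areg, a growth factor of the epidermal growth factor family, and less S100a9, an alarmin of granulocytes and young monocytes. Areg rose from 2.14 and 1.27 to 11 and 14.5 CPM (log2 fold change 2.88 ± 0.28, adjusted p = 0.0124). S100a9 fell from 5.65 and 7.07 to 1.33 and 0.723 (-2.54 ± 0.35, 0.0436). Of 10827 genes 12 passed, 4 higher and 8 lower. Commd10 rose (1.97 ± 0.12, 0.000347; 65.8, 55.1, 15.2 and 15.7 CPM) and Olfr56 fell (-4.08 ± 0.25, 0.000347). Sva had 42 UMIs against 0 (at least 24.7-fold higher, 0.0270). Atp5k (-0.84 ± 0.09, 0.0162), Ndufb1-ps (-0.70 ± 0.08, 0.0267) and Pet100 (-0.71 ± 0.09, 0.0295) fell, while the list of oxidative phosphorylation was not called (0.256). Sva (0.0599) and S100a9 (0.0578) did not pass without KO replicate 1, Pet100 (0.0727) without WT replicate 1, nor S100a9 (0.0748) without WT replicate 2. The counts were 26, 91, 25 and 28 without each library in turn, and 37 by DESeq2. With the highest doublet scores left out, 6 of the 12 passed. The myeloid suppressor list, which holds S100a9, was lower in 11 of 18 members (median -0.18, adjusted p = 5.7e-05; 0.715 with an estimated correlation), with S100a8 at -1.64 ± 0.40 and the decoy receptor Il1r2 at -0.55 ± 0.13. The neutrophil RNA list, which shares such genes, was lower in 7 of 7 (median -0.55, 1.1e-10; 0.715 with an estimated correlation). Its share of UMIs in these cells was 0.0223, 0.0249, 0.0294 and 0.0290%. It holds S100a8 and S100a9, and doublets largely remain. Whether the S100a9 RNA came from monocyte-like cells or from neutrophils in the same droplets was not tested. Hypoxia genes were lower in 16 of 17 (median -0.18, 3.4e-06; 0.715 with an estimated correlation), with Ddit4 (-0.85 ± 0.17) and the vessel growth factor Vegfa (-0.88 ± 0.26). Glycolysis genes were lower in 15 of 15 (median -0.13, 5.6e-05; 0.715 with an estimated correlation), with Hk2 (-0.59 ± 0.13) and Slc16a3 (-0.19 ± 0.08). Alternative activation genes were lower in 9 of 14 (median -0.20, 0.000454; 0.715 with an estimated correlation), with Chil3 (-0.67 ± 0.10), Arg1 (-0.86 ± 0.22) and Retnla (-2.18 ± 0.51). Adjusted over the list alone, 4 of these were lower and 1 was higher.

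Cluster 1, led by Mmp12, Mgl2, Ccl17, H2-Eb1 and Retnla, took 8.89, 14.3, 17.7 and 13.2% of cells, and Commd10 and Pdlim4 alone passed in it. Commd10 rose from 24.3 and 25.2 to 95.2 and 82.2 CPM (log2 fold change 1.85 ± 0.11, adjusted p = 0.00078), and Pdlim4 fell from 12.0 and 15.7 to 1.37 and 2.04 (-3.08 ± 0.29, 0.0186). Without each library in turn 21, 132, 133 and 16 genes passed, these 2 among them, and DESeq2 called 34. In simulations 43 of 173 calls without KO replicate 1 were false in this cluster. With equal numbers of cells only 1 of Commd10 and Pdlim4 passed, and both kept their direction. Sva (at least 23.8-fold higher, 0.0957), Hspa1a (-0.82 ± 0.11), Pet100 (-0.66), Ndufb1-ps (-0.67; all 0.0957), Ifi44 (0.62 ± 0.10, 0.148) and Rnaset2b (1.25 ± 0.21, 0.157) did not pass. Chemokine genes, which draw in other white blood cells, were lower in 15 of 18 (median -0.47, adjusted p = 1.0e-07; 0.715 with an estimated correlation). The monocyte attractants Ccl7 (-0.55 ± 0.10) and Ccl2 (-0.52 ± 0.17) and Ccl9 (-0.46 ± 0.12) were among them, and 2 passed adjusted over the list alone. NF-kB and inflammatory genes were lower in 17 of 21 (median -0.14, 0.00369; 0.715 with an estimated correlation), with Nfkbia at -0.25 ± 0.08 and the neutrophil attractant Cxcl2 at -0.48 ± 0.18. Stress genes of dissociation were lower as well, in 20 of 24 (median -0.14, 3.3e-06; 0.715 with an estimated correlation), with Hspa1b at -0.74 ± 0.11. Mitochondrially encoded genes were lower in 11 of 11 (median -0.15, 1.3e-06; 0.715 with an estimated correlation).

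Cluster 3, led by Ccl12, Ifit1bl1, Cxcl10, Ifit2 and Rsad2, had 23 passing genes of 10552, with 7 higher and 16 lower. Fabp4, a fatty acid carrier of lipid-loaded macrophages, fell from 12.0 and 14.2 to 2.89 and 1.90 CPM (log2 fold change -2.37 ± 0.27, adjusted p = 0.00475). Commd10 (2.35 ± 0.11, 3.3e-06), Sva (39 UMIs against 0, at least 18.1-fold, 0.0270) and the RNase gene Rnaset2a (1.33 ± 0.21, 0.0308) rose. Olfr56 (-4.41 ± 0.28, 4.0e-05), Pdlim4 (-4.21 ± 0.29, 5.3e-05) and the RNA polymerase subunit gene Polr2l (-1.06 ± 0.10, 0.00164) fell. Leaving out each library in turn gave 197, 281, 86 and 84 genes, holding 22, 23, 23 and 23 of the 23, and DESeq2 called 32. Of the 23, 8 passed with the replicate numbers crossed as a block, 14 with doublet calls kept, 15 with equal numbers of cells and 17 with thinned cells. Lipid-associated genes were lower in 16 of 19 members (median -0.13, adjusted p = 4.0e-07; 0.715 with an estimated correlation). Fabp4 passed over all genes and 6 passed adjusted over the list alone, with Spp1 at -0.88 ± 0.18 and Fabp5 at -0.50 ± 0.14. Hypoxia genes were lower in 16 of 17 (median -0.22, 2.5e-06; 0.715 with an estimated correlation), with Ndrg1 (-0.50 ± 0.11), Ddit4 (-0.81 ± 0.19) and Vegfa (-0.56 ± 0.18). Genes of MHC class II, which shows peptides to CD4 T cells, were higher in 8 of 10 (median 0.22, 0.000323; 0.715 with an estimated correlation), with their master regulator Ciita at 0.41 ± 0.11 and H2-Eb1 at 0.30 ± 0.11. Mitochondrially encoded genes were lower in 11 of 11 (median -0.15, 9.5e-07; 0.715 with an estimated correlation) and took 1.92, 1.72, 2.04 and 1.94% of UMIs.

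Cluster 5, led by Inhba, Cxcl2, Ptgs2, Clec4e and Cd14, had Commd10 as its 1 passing gene (log2 fold change 2.31 ± 0.14, adjusted p = 0.000221), and it passed without each library in turn. The counts were then 138, 223, 43 and 31, and DESeq2 called 12. Nt5dc2 (-1.13 ± 0.17), the clotting factor gene F7 (-0.97 ± 0.16) and Olfr56 (-3.62 ± 0.59) were lower without passing (all 0.148). MHC class II genes were higher in 9 of 10 members (median 0.40, adjusted p = 5.6e-07; 0.715 with an estimated correlation), and 6 passed adjusted over the list alone. H2-Eb1 was at 0.52 ± 0.13, H2-DMb1 at 0.43 ± 0.12 and Ciita at 0.58 ± 0.16. Hypoxia genes were lower in 16 of 18 (median -0.23, 2.1e-05; 0.715 with an estimated correlation), with Bnip3 (-0.39 ± 0.13) and Egln3 (-0.49 ± 0.16), and none passed adjusted over the list alone. Alternative activation genes were lower in 12 of 14 (median -0.32, 0.00124; 0.715 with an estimated correlation). The arginase gene Arg1, which depletes arginine, was at -1.67 ± 0.38 and Retnla at -2.31 ± 0.68. Neutrophil RNA was lower in 4 of 5 members (median -0.30, 0.000115; 0.715 with an estimated correlation), a call lost without KO replicate 2, at 0.0493, 0.0445, 0.0574 and 0.0569% of UMIs. Mitochondrially encoded genes were lower in 9 of 11 (median -0.04, 0.0294; 0.715 with an estimated correlation), a call lost without KO replicate 1, WT replicate 1 or WT replicate 2. Retnla reversed to 0.82 with doublet calls kept and to 0.80 at a mitochondrial limit of 20%.

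Conventional dendritic-like cells of the KO libraries held more RNA of dividing cells. S phase genes were higher in 22 of 22 tested members, with a median log2 fold change of 0.96, and genes of G2 and M phase in 8 of 8, with a median of 1.11. The replication genes Uhrf1 (1.74 ± 0.28), Mcm3 (1.13 ± 0.20), Mcm6 (1.14 ± 0.24) and Rrm2 (2.53 ± 0.63) and the mitosis genes Birc5 (1.80 ± 0.45), Top2a (1.20 ± 0.31), Cdk1 (2.01 ± 0.52) and Mki67 (0.96 ± 0.28) were among them. Adjusted over the list alone, 13 S phase and 5 mitosis genes passed. Camera gave adjusted p values of 7.7e-23 and 3.8e-10, and 0.715 each with an estimated correlation. No gene of 9792 passed in edgeR, with 501 at an unadjusted p under 0.05 and 17 called by DESeq2. The smallest p belonged to Pclaf, a clamp-associated replication gene (2.87 ± 0.36, adjusted p = 0.0938), and Atp5k (-0.93 ± 0.12, 0.0938), ahead of Commd10 (1.20 ± 0.19), Cxcl2 (-2.22 ± 0.35) and Ndufb1-ps (-0.72 ± 0.12; all 0.128). Without KO replicate 1, KO replicate 2, WT replicate 1 and WT replicate 2, 388, 228, 40 and 5 genes passed. The cells had a median of 3621, 12755, 11867 and 12590 UMIs. Macrophage RNA took 0.587, 0.594, 0.463 and 0.481% of UMIs in these cells, and mitochondrially encoded genes were lower in 11 of 11 (median -0.16, 8.3e-05; 0.715 with an estimated correlation).

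Migratory dendritic-like cells, which carry antigen to lymph nodes, had 6 genes higher and 4 lower among 7638. The chemokine gene Ccl6 rose from 18.6 and 24.9 to 84.2 and 95.6 CPM (log2 fold change 2.02 ± 0.23, adjusted p = 0.00752). Thbs1 (2.40 ± 0.32, 0.0160) and the clotting factor gene F13a1 (3.27 ± 0.46, 0.0196), both abundant in monocytes, rose with it. Gzmb, a protease of killer cells, fell from 61.3 and 39.7 to 3.87 and 11 (-2.80 ± 0.42, 0.0242). The other 3 lower genes were 2 of ribosomal proteins and 1 receptor segment. Leaving out each library in turn gave 190, 240, 44 and 73 genes, holding 10, 10, 8 and 8 of the 10, and DESeq2 called 13. None of the 10 passed at Leiden resolution 0.5 or with the highest doublet scores left out, where 3 were not tested and 7 kept their direction. Macrophage RNA took 0.360, 0.237, 0.186 and 0.235% of UMIs here, and T cell RNA 0.00857, 0.0160, 0.0209 and 0.0205%. Type I interferon genes were higher in 24 of 26 (median 0.40, adjusted p = 8.6e-12; 0.715 with an estimated correlation). Ifit1 (0.62 ± 0.15), Ifi44 (0.73 ± 0.19), Oasl1 (0.57 ± 0.15) and Slfn5 (0.49 ± 0.14), which block viral RNA or cell growth, were among the 11 that passed adjusted over the list alone.

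In CD8-like T cells, Xcl1, Ccl1, Nr4a3 and Fosb, which T cell receptor signals can switch on, passed as lower, and each lost its call without 1 or more libraries. Xcl1, which attracts cross-presenting dendritic cells, fell from 672 and 889 to 388 and 169 CPM (log2 fold change -1.49 ± 0.25, adjusted p = 2.3e-05). The chemokine gene Ccl1 fell from 216 and 29.5 to 5.04 and 8.26 (-4.22 ± 0.43, 3.6e-14). The factor genes Nr4a3 (-1.54 ± 0.29, 0.000471; 26.5, 32.0, 87.7 and 82.6 CPM) and Fosb (-1.37 ± 0.29, 0.00388) fell as well. Rnaset2a (1.64 ± 0.27, 1.2e-05), Rnaset2b (1.30 ± 0.27, 0.00192) and Tgtp1 (2.09 ± 0.50, 0.0202) rose. Of 7946 genes 21 passed, 13 higher and 8 lower, and in 16 of them both KO values lay beyond both WT values. Granzyme genes did not separate the groups: Gzma stood at 165, 835, 258 and 117 CPM (1.40 ± 0.28, 0.00142) and Gzmf at 0, 262, 40.9 and 0 (2.46 ± 0.41, 2.0e-05). Without KO replicate 2 both reversed, Gzma to -0.21 (adjusted p = 1.00) and Gzmf to -8.24 (6.4e-05), and without WT replicate 2 neither passed. Leaving out each library in turn gave 12, 36, 17 and 3 genes, holding 7, 15, 8 and 2 of the 21, and DESeq2 called 2. Of the 21, 2 passed with thinned cells, 2 with equal numbers of cells and 5 at the 20% mitochondrial limit. Ccl1 did not pass without WT replicate 1 (-2.11, 0.0943), nor Xcl1 without KO replicate 2 (0.457) or WT replicate 2 (0.623). Nr4a3 lost its call without KO replicate 1 (0.246) or WT replicate 2 (0.0810), and Fosb did without KO replicate 1 (0.862), WT replicate 1 (0.252) or WT replicate 2 (0.0942). Rnaset2a lost its call without KO replicate 1 (0.407) or WT replicate 2 (0.180), and Rnaset2b and Tgtp1 did without KO replicate 1 (both 1.00), WT replicate 1 (0.226 and 0.561) or WT replicate 2 (0.231 and 0.851). Immediate early genes were lower in 15 of 18 (median -0.26, adjusted p = 2.0e-05; 0.715 with an estimated correlation), with Nr4a1 at -0.83 ± 0.28. Stress genes of dissociation, a list that shares Nr4a1, Fosb and other members with the immediate early list, were lower in 19 of 23 (median -0.19, 1.3e-05; 0.715 with an estimated correlation), with Hspa1b at -0.68 ± 0.24. Mitochondrially encoded genes were lower in 10 of 11 (median -0.17, 0.00223; 0.744 with an estimated correlation), a call lost without KO replicate 2 or WT replicate 1, at 2.70, 2.81, 3.14 and 2.87% of UMIs. The class pooled 2 subclusters whose mix differed between libraries. The one with Xcl1, Ccl3, Ifng and genes of dividing cells at its top held 27 of 103, 38 of 103, 122 of 248 and 35 of 153 cells, and levels of Xcl1 and of genes that go with it carry that mix as well. The cytotoxicity list, higher in 11 of 18 (median 0.21, 0.0011; 0.728 with an estimated correlation), turned lower without KO replicate 2 or WT replicate 2.

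Natural killer-like cells had 11 passing genes of 5870, 3 higher and 8 lower, 5 of the lower ones ribosomal and 1 mitochondrial. Gzmf, a granzyme gene of activated killer cells, was at 0 in both KO libraries against 156 and 77.3 CPM (0 against 166 UMIs, at least 34.8-fold lower, adjusted p = 8.7e-06). Serpinb9b, a granzyme inhibitor gene, rose from 73.0 and 40.6 to 110 and 204 (log2 fold change 1.45 ± 0.27, 0.0196). Rnaset2b (1.37 ± 0.23, 0.00550) and Rnaset2a (1.55 ± 0.26, 0.00550) rose, and Ndufb1-ps fell (-0.83 ± 0.16, 0.0251). Leaving out each library in turn gave 39, 46, 12 and 19 genes, holding 9, 9, 5 and 8 of the 11, and DESeq2 called 6. Calls were lost for Rnaset2a without KO replicate 1 (0.0607), for Serpinb9b without KO replicate 2 (0.267) or WT replicate 2 (0.0719), and for Ndufb1-ps without KO replicate 1 (0.0594) or WT replicate 1 (0.363). Stress genes of dissociation were lower in 17 of 22 (median -0.21, 0.00125; 0.715 with an estimated correlation), with the phosphatase gene Dusp1 at -0.59 ± 0.19 and the cytokine signalling inhibitor Socs3 at -0.78 ± 0.26. Mitochondrially encoded genes were lower in 10 of 11 (median -0.17, 0.000737; 0.715 with an estimated correlation), at 2.81, 2.89, 3.05 and 3.16% of UMIs. Ribosomal protein RNA took 8.74, 8.01, 9.11 and 8.91% and macrophage RNA 0.567, 0.508, 0.460 and 0.428%. The cytotoxicity list, higher in 14 of 19 (0.0394; 0.715 with an estimated correlation), turned lower without WT replicate 1.

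CD4-like T cells outside the regulatory class also held less immediate early RNA, lower in 15 of 16 members with a median log2 fold change of -0.50. Nr4a3 (-2.39 ± 0.47) and Nr4a1 (-1.88 ± 0.37), which report recent T cell receptor signals, were the lowest and did not pass over all genes (both adjusted p = 0.0741). Nr4a2 (-1.71 ± 0.46) and Jun (-0.69 ± 0.20) went with them, and 6 passed adjusted over the list alone. Camera gave an adjusted p of 1.8e-09, and 0.715 with an estimated correlation. Naive and memory genes were lower in 13 of 15 (median -0.38, 8.3e-05; 0.715 with an estimated correlation), with the interleukin-7 receptor Il7r at -0.41 ± 0.14 and the survival gene Bcl2 at -0.71 ± 0.27, and none passed adjusted over the list alone. Stress genes of dissociation, a list that shares Nr4a1, Jun and other members with the immediate early list, were lower in 20 of 23 (median -0.25, 3.4e-07; 0.715 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 11 (median -0.26, 1.2e-05; 0.715 with an estimated correlation), and ribosomal protein genes in 24 of 26 (median -0.09, 7.2e-06; 0.715 with an estimated correlation). Ribosomal protein RNA took 8.02, 8.05, 8.87 and 8.94% of UMIs. Of 6021 genes 8 passed, all lower: 7 of ribosomal proteins and Tmsb10, an actin-binding peptide gene (-0.58 ± 0.10, adjusted p = 0.0425). Tmsb10 did not pass without WT replicate 1 (0.374) or WT replicate 2 (0.818). The counts without each library in turn were 59, 94, 3 and 8, holding 8, 8, 0 and 4 of the 8, and DESeq2 called 10. Pim1 (-0.86, 0.106), Txn1 (0.93, 0.139) and Fyb (0.65, 0.141) did not pass. With equal numbers of cells 0 of the 8 passed, all in the same direction as before. KO libraries gave 52 and 61 such cells, and in simulations edgeR recovered 20.9% of 2-fold changes in this class.

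Regulatory T-like cells had Rnaset2a as their 1 passing gene of 9810, which rose from 64.4 and 57.7 to 228 and 125 CPM (log2 fold change 1.56 ± 0.21, adjusted p = 0.0276). It did not pass at the 20% mitochondrial limit, where 0 genes passed. Without each library in turn 120, 163, 55 and 44 genes passed, this 1 among them, and DESeq2 called 4. The polyamine enzyme gene Srm (1.16 ± 0.21), the histone gene Hist1h1b (1.01 ± 0.19) and Bloc1s1 (1.32 ± 0.25) were higher without passing (all 0.0914). Polr2l (-1.90 ± 0.29, 0.0541), Pet100 (-0.82 ± 0.13, 0.0838) and Hspa1b (-0.94 ± 0.16, 0.0914) were lower without passing. Genes of oxidative phosphorylation, the respiratory chain, were higher in 22 of 23 (median 0.28, adjusted p = 3.4e-07; 0.715 with an estimated correlation). Ndufs8 was at 0.49 ± 0.13 and Uqcrfs1 at 0.42 ± 0.13, and 1 member passed adjusted over the list alone. The class pooled 4 subclusters, and the one led by genes of dividing cells held 47 of 238, 22 of 124, 61 of 436 and 67 of 483 cells, a mix that these values carry as well. Genes of activated regulatory T cells were lower in 17 of 21 (median -0.11, 0.0205; 0.715 with an estimated correlation), a call lost without KO replicate 1.

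In neutrophil-like cells no gene of 5473 passed, and the chemokine genes Cxcl2 and Ccl3 were among those with the smallest p. Cxcl2 stood at 3423 and 4449 against 11588 and 8997 CPM (log2 fold change -1.39 ± 0.20) and Ccl3 at 1064 and 1248 against 2477 and 2579 (-1.13 ± 0.17). Both had an adjusted p of 0.0784. At an unadjusted p under 0.05 there were 441 genes, and DESeq2 called 3. With the highest doublet scores left out 66 passed, with the replicate numbers crossed as a block 17, with equal numbers of cells 6 and at the 20% mitochondrial limit 5. Without KO replicate 1, KO replicate 2, WT replicate 1 and WT replicate 2 there were 33, 185, 0 and 5. NF-kB and inflammatory genes were lower in 20 of 22 (median -0.45, adjusted p = 5.7e-12; 0.715 with an estimated correlation), with Cxcl1 at -2.75 ± 0.57 and Ccl4 at -1.05 ± 0.25, and 8 passed adjusted over the list alone. Glycolysis genes were lower in 15 of 15 (median -0.50, 1.9e-07; 0.715 with an estimated correlation), with Hk2 at -1.23 ± 0.22 and the glucose carrier Slc2a1 at -0.71 ± 0.24. Hypoxia genes were lower in 12 of 14 (median -0.32, 0.00160; 0.715 with an estimated correlation). Type I interferon genes were lower in 22 of 26 here (median -0.22, 0.000169; 0.715 with an estimated correlation), with Oasl1 at -0.64 ± 0.19 and Rsad2 at -0.59 ± 0.18, and none passed adjusted over the list alone. The difference from macrophage-like and migratory dendritic-like cells, where this list was higher, was not tested. Genes of neutrophils themselves were lower in 8 of 9 (median -0.55, 6.1e-06; 0.715 with an estimated correlation), with G0s2 at -1.38 ± 0.22 and the histamine enzyme gene Hdc at -0.79 ± 0.21. They took 2.01, 2.87, 3.1 and 2.66% of UMIs. Macrophage RNA took 1.66, 1.49, 1.35 and 1.24%, and ribosomal protein genes were higher in 21 of 26 (median 0.36, 2.0e-06; 0.715 with an estimated correlation). Olfr56 was at 0 in both KO libraries against 37.9 and 44.7 CPM (at least 10.5-fold lower, 0.0784), and Mtln (2.91 ± 0.58), Tmem176a (2.31 ± 0.47) and Commd10 (2.24 ± 0.46; all 0.244) were higher without passing.

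**Figure D3:**
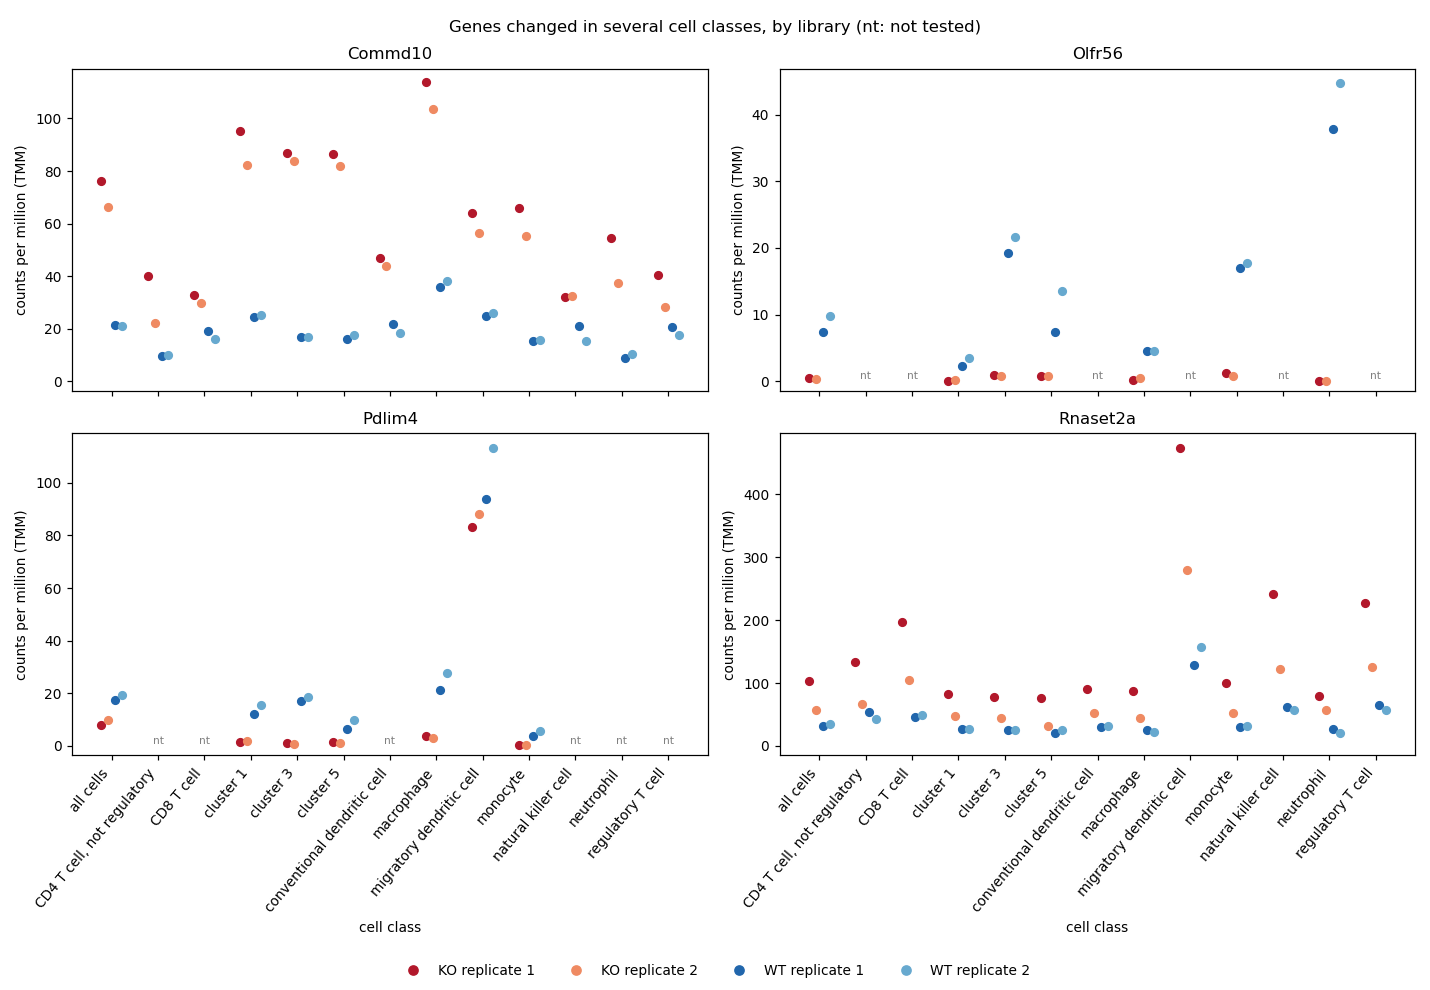
CPM (y axis, TMM-scaled) of Commd10, Olfr56, Pdlim4 and Rnaset2a in the 4 libraries of every tested cell class (x axis), 1 point per library. Commd10 stands at 76.2 and 66.2 in the KO libraries over all cells against 21.4 and 21.1 in the WT libraries.

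Of 20 genes called in 2 or more classes, Commd10 and Rnaset2a were each called in 5. Commd10 and Rnaset2a were higher in the KO libraries in 12 of 12 classes. Pdlim4 was called in 3 and Olfr56 in 2, each lower in 6 of 6 tested classes. In migratory dendritic-like cells, a class chosen after its values were seen, Pdlim4 was at 83.3, 88.3, 93.7 and 113 CPM and did not pass. The median of Rnaset2a over classes was 1.37, and 0.84 without KO replicate 1. Of these 20 genes, 10 fell by smaller amounts in up to 5 classes each (median -0.69), among them Ndufb1-ps, Atp5k, Pet100, Polr2l and Hspa1b beside ribosomal and mitochondrial genes.

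**Figure D4:**
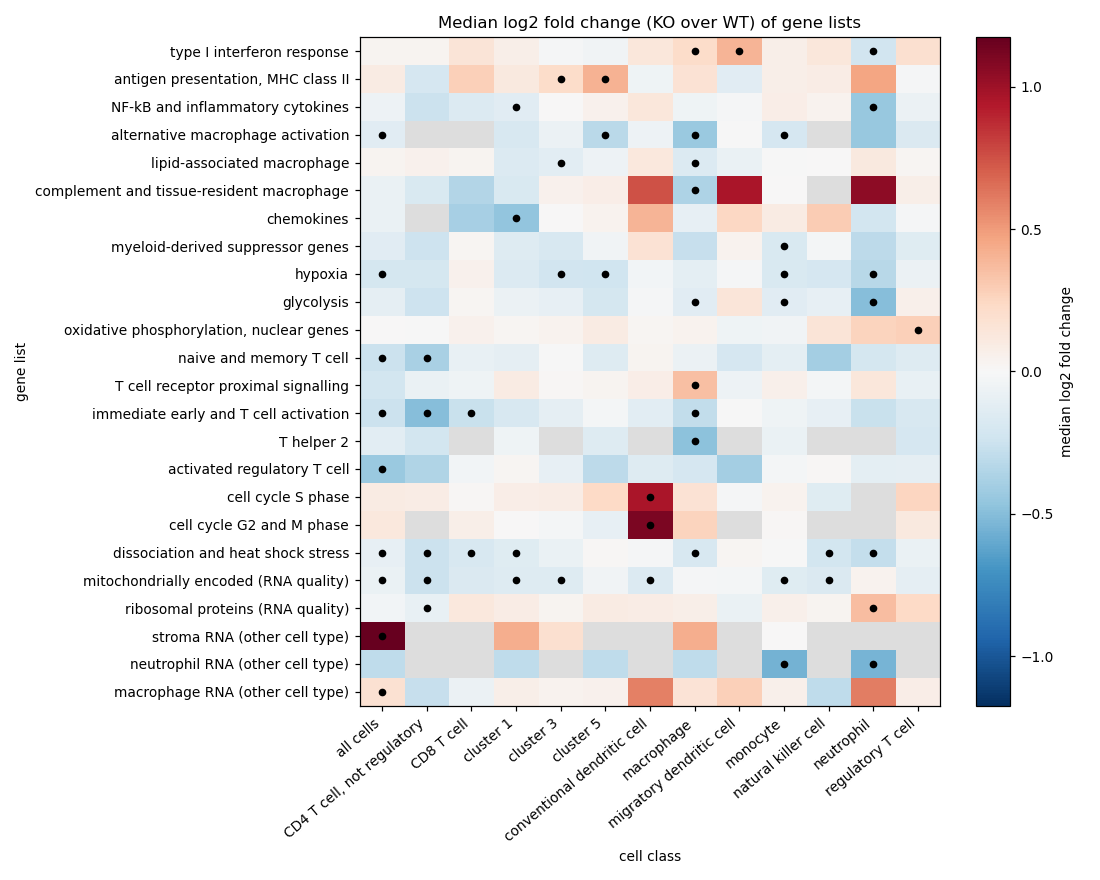
Median log2 fold change (colour, KO over WT) of gene lists (y axis) in the tested classes (x axis), grey where fewer than 5 genes were tested. Black points mark the 56 calls by camera at a correlation of 0.01 that passed without each library in turn, none of which passed with an estimated correlation.

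The set tests set 39 lists against the 13 sets of cells, and 151 of 440 pairs passed by camera at a correlation of 0.01, 52 higher and 99 lower. With an estimated correlation 0 passed, with 14 at an unadjusted p of 0.05 or less. With fry 0 passed, with 32 at an unadjusted p of 0.05 or less. In simulations without changed genes, the estimated correlation gave an unadjusted p under 0.05 for 1 of 39 lists over all cells and 0 in every class. Neither test was run on simulated lists that changed. How many such lists they would find is unknown, so 0 passing does not show unchanged lists. The 0.715 beside most lists is the lowest adjusted p of called lists with an estimated correlation. Lists share it, so it does not rank them. On simulated counts with no changed gene, camera at a correlation of 0.01 still called 3 of 39 lists over all cells. It called 1 in cluster 1, 1 in natural killer-like cells and 0 in the other classes, adjusted within each. Genes were drawn independently there, so false calls from correlated genes of a list were not measured. Of the 151 calls, 56 passed in the same direction without each library in turn, and the others lost their call without 1 or more libraries: 44 without KO replicate 1, 46 without KO replicate 2, 36 without WT replicate 1 and 37 without WT replicate 2. Of the 151, 21 turned to the opposite direction without 1 or more libraries. Each of these fits rests on 1 library in a group, so the 56 are those that lost no call and not lists shown to be stable. Every list result given for a class belongs to these 56 unless a lost call is stated. Members said to pass adjusted over the list alone belong to lists that were called on the same counts. Their numbers are therefore no separate support for a list, and that adjustment does not allow for the choice of lists.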

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

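The tests of DNA near Shb, of strain segments in general, of sex, those in cells with at least 3000 UMIs and all 3 tests of cluster 0 were chosen after the result was seen, and the others were written down before.

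Gzmf, a granzyme gene, had opposite KO effects in natural killer-like and CD8-like cells, and an interaction test in edgeR over 7996 genes put the difference at -12.811 ± 1.1551 on the log2 scale (adjusted p = 1.8e-10). Counts of 0 in both KO libraries of natural killer-like cells and in KO replicate 1 and WT replicate 2 of CD8-like cells make these fitted values no bounds. The CD8-like value rests on KO replicate 2 alone, without which Gzmf was lower there too (-8.24), so the difference in direction is not established.

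Large changes of the same genes across classes form the first pattern weighed: 10 genes called in 2 or more classes at a median absolute log2 fold of at least 0.9, among them Commd10, Rnaset2a, Rnaset2b, Pdlim4, Olfr56, Tgtp1 and Sva. DNA carried along with the targeted locus was argued against, as 0% of them lay within 20 Mb of Shb, and so was the sex of the mice, as 4 genes of the Y chromosome took 0.0437 CPM in KO and 0.0600 CPM in WT libraries, although 1 of the 10 is a predicted gene placed there, with 0 UMIs in WT against 46 and 44 in KO libraries in cluster 3 and macrophage-like cells. Low-UMI droplets of KO replicate 1 were argued against for the set, since 92.5% of its median absolute fold was kept without that library (2.10 of 2.27). Tgtp1 (1.60 to 0.82), Rnaset2a (1.37 to 0.84) and Rnaset2b (1.25 to 0.88) fell without it. They kept a median of 99.4% in cells with at least 3000 UMIs. That cut left in most cells of most classes, with KO replicate 1 medians of 8732.5 UMIs in cluster 1 and 9272.5 in monocyte-like cells. It could hardly move these folds, so it does not decide whether these genes rest on that library. DNA segments of another strain that differ between the mice of the groups stay open: of 8 independent loci 2 lay within 10 Mb of another, and 2486 of 10000 random sets held as many, and on chromosome 11, where Olfr56, Tgtp1 and Pdlim4 lie from 48978889 to 54069014, 12.8% of 227 neighbouring genes had an unadjusted p under 0.05 against 7.54% elsewhere, short of the 2 times set beforehand, with no test of this against chance. Rnaset2a and Rnaset2b, which are near-identical copies, and Olfr56 and Tgtp1, which overlap, were counted once each among the loci, Gzmf goes both ways, and an effect of Shb loss on each gene stays open and untested. DNA at and around the Vav1-cre transgene was not tested. These tests therefore leave it open as a source for Commd10 and the others, apart from any effect of Shb loss.

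Smaller losses form the second pattern: 10 genes fell in 2 or more classes with a median log2 fold of -0.69, and their longest transcripts had a median of 766.5 nt against 3091 nt for all tested genes, from 348 nt to 2803 nt (Hspa1b). The tables argue against a loss of ribosomal protein RNA as a whole. Of such genes, 77 with a longest transcript of at least 700 nt had a median of -0.01 over all cells (-0.0095661), far above the -0.69. For the 10 genes as a set the tables also argue against the low depth of KO replicate 1, without which 102% of the median was kept. The median of Polr2l fell without that library (-0.85 to -0.55). It kept 92.4% in cells with at least 3000 UMIs, but that cut left in most cells of most classes and does not decide for this gene. A bias against short RNAs in library preparation stays open, and 3 of the 10 genes had a longest transcript under 500 nt. The longest annotated transcript of a gene can exceed the RNA present in the cells, so this length does not show that the others are long RNAs. As a test, 58 genes under 500 nt outside the ribosomal and mitochondrial groups had a median of -0.14, with 35 lower. Of matched random sets 0.04% were as low, but the median fell short of the -0.2 set beforehand. A smaller loss of ribosomal protein RNA stays open, as its share was 4.90 and 4.62% in KO against 5.36 and 5.11% in WT libraries and its list was called lower (adjusted p = 0.0032), a call lost without KO replicate 2 or WT replicate 1. Library preparation cannot be told apart from genotype here, because the labels give no batches.

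Cluster 0, which took 30.2% of KO replicate 1, is the third pattern, and genotype alone is argued against because KO replicate 2 held 1.59% (2.00 and 1.75% in WT). Damaged macrophages or monocytes stay open, since the median mitochondrial percent of its cells was 0.879 times that of macrophage-like cells (2.02 against 2.29%), within their spread, and cells over 10% had been removed before. Free RNA may be part of it: T cell RNA took 0.386 times its share in the other droplets of that library, neutrophil RNA 0.718 times, macrophage RNA 1.22 times and B cell RNA 0.153 times. These lie between what free RNA and what macrophage-like cells of low depth would give, so they cannot be told apart. Its droplets had a median of 1290.5 UMIs.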

How the results depend on the processing

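The minimum of 3000 UMIs, the highest doublet scores left out, fry and the crossed block were chosen after the data were seen. Over all cells 2 genes passed, against 153 with DESeq2, 192 with no filter, 10 with thinned cells, 4 with equal numbers of cells and 0 to 245 without a library. Summed over classes 100 passed, against 207 with DESeq2, 1567 with no filter, 66 at Leiden resolution 0.5 (10 classes, with 76 in the same 10 before) and 331 to 2111 without a library. The cause of these shifts was not tested. With replicate number as a block, 0 genes passed over all cells and 476 over classes, and with the numbers crossed 5 and 621, and the correlation of deviations between equal numbers ran from -0.26 to 0.09 over classes, so equal numbers showed no sign of shared pairs, and pairs across numbers stay open. For shares, 2 classes passed, against 0 with TMM over classes, immune classes alone, the 20% mitochondrial limit, Leiden resolution 0.5, the block, the highest doublet scores left out and limma on logit shares, 1 (fibroblast-like) with at least 3000 UMIs and 0 to 23 without a library. For lists, 151 passed, against 0 with an estimated correlation and 0 with fry, and 151, 112 and 144 with the block, thinned cells and at least 3000 UMIs. Without a library 154 to 188 passed. The KO minus WT differences of the T cell ratios moved by less than the larger SD between replicates. The Shb level was not compared with that spread. The ratio of CD8-like to regulatory T-like cells itself rose to 0.965 in KO and 0.720 in WT with cells called by their own UMIs. Of 3101 alternative values of 187 named gene and class pairs, 2413 kept direction and side of the limit, 174 no longer passed, 510 newly passed and 4 reversed. Most of these pairs had not passed to begin with. Of the 812 values of the 49 pairs that had passed, 636 kept direction and side of the limit, 174 no longer passed and 2 reversed. The reversals were Retnla in cluster 5 (0.82 with doublet calls kept, 0.80 at the 20% limit), and without KO replicate 2 in CD8-like cells Gzmf (-8.24, with a range of -8.24 to 10.045 without a library) and Gzma (-0.21, with a range of -0.21 to 2.13). At resolution 0.5, clusters 3 and 5 merged and have no separate values. Depth limits Shb in T cells and genes of the small lymphocyte classes.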

Other observations

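The 4 samples of experiment 2 enter no comparison. Their lists of barcodes held 53152 and 36270 entries for KO and 46355 and 35790 for WT, more than any of the 4 libraries of experiment 1, the largest of which held 12052.

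Plasmacytoid dendritic-like cells, which make interferon, took 1.95, 0.531, 0.652 and 0.730% of kept cells, and gamma-delta T or innate lymphoid-like cells 0.175, 0.850, 0.765 and 0.454%, in the order KO replicate 1, KO replicate 2, WT replicate 1, WT replicate 2. Neither passed the test of cell numbers with edgeR (log2 fold change 0.87 ± 0.95, adjusted p = 0.801, and -0.32 ± 0.98, 0.842). Unnamed cluster 13, led by Rhox5, Cald1 and Krt8 and thus unlike white blood cells, took 3.82, 1.13, 1.09 and 1.07% and did not pass (1.21 ± 0.95, 0.801).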
